A study of Arabidopsis thaliana with 24 samples.

How the data were processed

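Gene expression was measured in rosette leaves of 24-day-old Arabidopsis thaliana plants of the accession Col-0 (WT) and of d14-1, a mutant of the strigolactone receptor D14. Aerial parts were detached and left to dry for 0, 2 or 4 h, per the labels' protocols. Each of the 6 groups (2 genotypes at 3 times) had 4 independent biological replicates, per the series' design text, which gives 24 arrays with 1 sample each. Groups and replicate numbers were taken from the sample titles. The titles and protocols name d14-1 for the mutant samples, while a description field of these samples names kai2-2, a mutant of the related karrikin receptor gene, so both genes were checked first.

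Total RNA was labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels' protocols. The scanner intensity values were made with Agilent Feature Extraction 10.7.3.1, per the file headers. In that output the processed intensity of a spot is background-subtracted and detrended within the array, per the file headers, with no scaling between arrays. The deposited table of the whole series holds log2 values whose scale and centring were found by setting them against the scanner values. They are log2 processed intensities minus the array's 75th percentile and minus each probe's median over the 24 arrays. Of its columns 4, all of the d14 0 h group, matched another array of the same group better than their own, so the deposited table was used only as an alternative. Column medians of the table ranged from -0.11 (WT 4 h, replicate 1) to 0.33 (WT 0 h, replicate 4).

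The main values were log2 processed intensities minus each array's 75th percentile, so every level is relative to its array. Control spots were left out, spots flagged as outliers were set to missing (51 values), and spots of a probe were averaged. Of 43603 probes, 35410 were tied to 1 locus, 500 to several and 7693 to none, through RefSeq accessions (34197) or locus codes (1213), and names came from the RefSeq gene table used here. Where a symbol belongs to several loci, the locus is given. The probe with the highest mean signal stood for a locus, and a gene was tested when that probe was well above background on all 4 arrays of at least 1 group. This left 19744 genes, of which 17142 were well above background on all 24 arrays. Where a gene was well above background on only some arrays of a group, the number is given, and its fold change there is less certain.

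Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), from the group means of all 24 arrays in a single fit with 18 residual and 2.25 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, a call is an adjusted p under 0.05, and calls of at least 2-fold were also counted. Log2 fold changes are given with their standard error (SE). The comparisons were d14 against WT at each time, 2 h and 4 h against 0 h in each genotype, and the interactions, which are the differences between the d14 and WT responses. Comparisons of 4 h against 2 h were added after seeing the data, because they use no 0 h array. The WT and d14 responses were also compared across genes by correlation and by a total least squares slope.

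Before the data were examined, 32 gene lists were fixed, with 520 loci, of which 500 were tested. They cover strigolactone biosynthesis and breakdown, strigolactone and karrikin signalling, abscisic acid (ABA) synthesis, breakdown and transport, ABA receptors, clade A protein phosphatases 2C, SnRK2 kinases and ABF factors, dehydration- and ABA-response effectors, dehydration-response transcription factors, osmolyte metabolism, photosynthesis, the flavonoid and anthocyanin pathway, cuticle and wax, stomatal development, guard-cell function, senescence and chlorophyll breakdown, jasmonate, salicylate and defence, heat shock, auxin, cytokinin, the circadian clock, cell division, aquaporins, antioxidant enzymes, aliphatic and indole glucosinolates, and reference genes. Markers of flower and inflorescence, shoot meristem, epidermis and trichome, phloem and xylem, and root were included because the sample could hold such cells. Each list was tested with limma's camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The genes named were fixed by rule before the data were examined. They are D14 and KAI2, the 5 largest rises and falls of each comparison among genes that passed the test and were well above background (without overlap between the groups, except for an interaction), the 4 members of each list with the largest change, and a fixed panel of hormone and stress genes.

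The alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the median, no filter on dim probes, a filter on all 24 arrays, the mean of all probes of a gene, all probes, only the groups compared, a trended and robust variance model, the replicate number as a block, the deposited table, an adjusted p under 0.01 and leaving out each array. Rescaling by the spike-in controls and fits of 1 scan day alone were added after seeing the data. The fit was tested on simulated arrays built from each gene's mean over all 24 arrays and its residual spread, with independent normal noise. Apart from the genes changed on purpose, these held no group, slide or time differences, unlike the real arrays. In them 85.1% of genes changed 2-fold were recovered for d14 against WT at 4 h and 8% of the calls were of unchanged genes. At 0 h these shares were 83.6% and 4.3%. Of genes changed 1.5-fold, 50.7% were recovered for d14 against WT at 4 h. For the interactions at 2 h and 4 h, 76.1% and 73.1% were recovered at 2-fold, and 50.7% and 40.3% at 1.5-fold. The number of arrays limits the precision. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.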

Results

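The series asks how leaves that lack the strigolactone receptor D14 differ from WT when they lose water. Strigolactones are plant hormones that restrain shoot branching and take part in drought responses. There were 24 arrays in 6 groups of 4, from WT and d14 rosette leaves at 0, 2 and 4 h after the aerial parts were detached. No leaves kept hydrated for 2 or 4 h were analysed here, so time of day and detachment changed together with water loss. Of 43803 non-control spots, a mean of 63.8% ± 0.87 (SD, n = 4) were well above background in WT at 0 h, 68.7% ± 1.68 in d14 at 0 h, and between 69.9% and 72.0% in the other groups. Replicates of a group correlated at r = 0.982 or more across genes, and no pair held identical values. Replicates 1 and 3 of WT at 4 h were the closest pair (r = 0.9974). The SD of their log2 difference was 0.218, against 0.372 to 0.405 in the other pairs of that group. In the next closest pair, WT 0 h replicates 3 and 4, it was 0.262. The first principal component held 69.9% of the variance and parted the 0 h arrays from the dehydrated ones, and the second, with 9.49%, parted 2 h from 4 h. On the third, with 6.93%, all WT arrays lay above all d14 arrays.

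**Figure D1:**
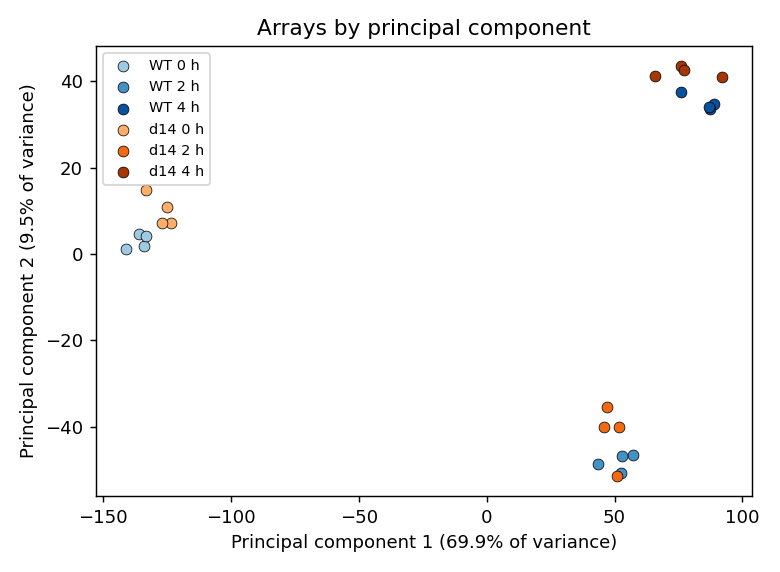
Position of the 24 arrays on the first 2 principal components (axes in component units, with the percent of variance), with 1 point per array coloured by genotype and time. The 0 h arrays lie apart from the dehydrated ones on component 1 (69.9% of the variance).

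Each group lay on a slide of its own (6 slides), so slide and group cannot be told apart. The WT 0 h slide stood apart from the rest. Its slope of log signal on log spike-in amount was 0.798 ± 0.011 (SD, n = 4), against 0.917 ± 0.013 in d14 at 0 h and 0.961 to 0.979 in the other groups. Its negative controls had a mean net signal of 55.6 ± 1.7 intensity units against 33.9 ± 1.5 in d14 at 0 h and 21.6 to 25.8 elsewhere. Every comparison with WT at 0 h rests on this slide. WT at 0 h, WT at 2 h and d14 at 0 h were scanned on 1 day and the other groups on another. Thus d14 against WT at 2 h, WT at 4 h against 0 h, both d14 responses, WT at 4 h against 2 h and the interactions other than that at 4 h cross the scan days. In fits of the arrays of 1 day alone there were 9607 genes d14 against WT at 0 h, 3072 genes d14 against WT at 4 h, 15291 genes WT 2 h against 0 h and 10417 genes d14 4 h against 2 h, against 9932, 3365, 15491 and 10350 in the fit of all arrays.

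**Figure D2:**
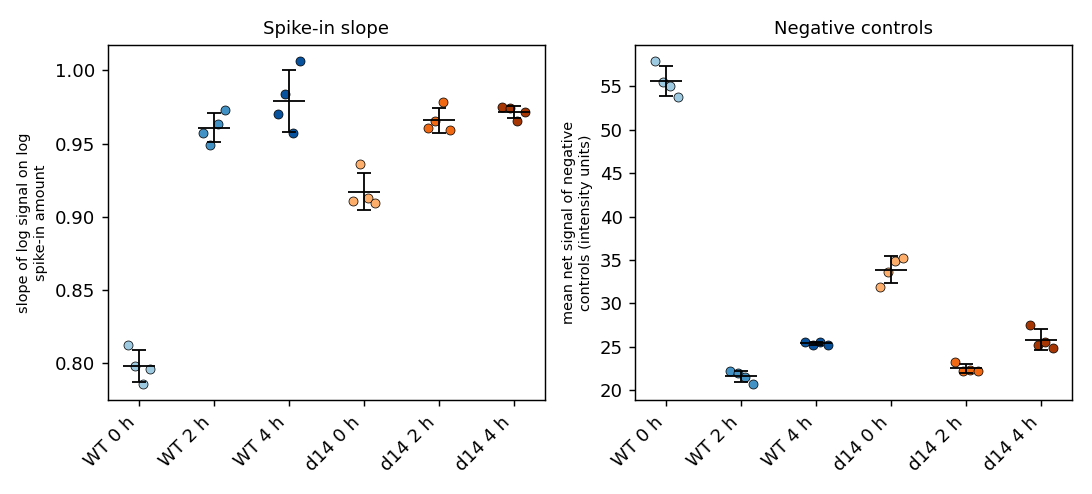
Slope of log signal on log spike-in amount (left) and mean net signal of negative controls in intensity units (right) for each array, with group mean and SD (n = 4). WT at 0 h has the lowest mean slope, 0.798, and the highest mean negative-control signal, 55.6.

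D14 was lower in d14 than in WT at every time, in the samples whose titles name d14-1. Its brightest probe, A_84_P76494 (chromosome 3, 1034657 to 1034716, TAIR10 per the file headers), stood at 2.77 ± 0.11 in WT and -0.31 ± 0.07 in d14 at 0 h (log2 relative to the array's 75th percentile, SD, n = 4). WT exceeded d14 8.44-fold at 0 h, 16.4-fold at 2 h and 23.9-fold at 4 h. The other 2 D14 probes, at 1034001 to 1034059 and 1034131 to 1034190, gave WT over d14 ratios of 9.77 and 11.3 at 0 h and 38.8 and 26.4 at 4 h. All 3 were well above background on every d14 array. Where the mutation lies relative to these probes is not given in the sources used here. KAI2, the karrikin receptor named in the mutant's description (probe on chromosome 4, 17617089 to 17617148), had a log2 fold change in d14 of -0.45 ± 0.09 (SE) at 0 h, -0.06 ± 0.09 at 2 h and 0.14 ± 0.09 at 4 h, with adjusted p = 0.000571, 0.639 and 0.336.

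**Figure D3:**
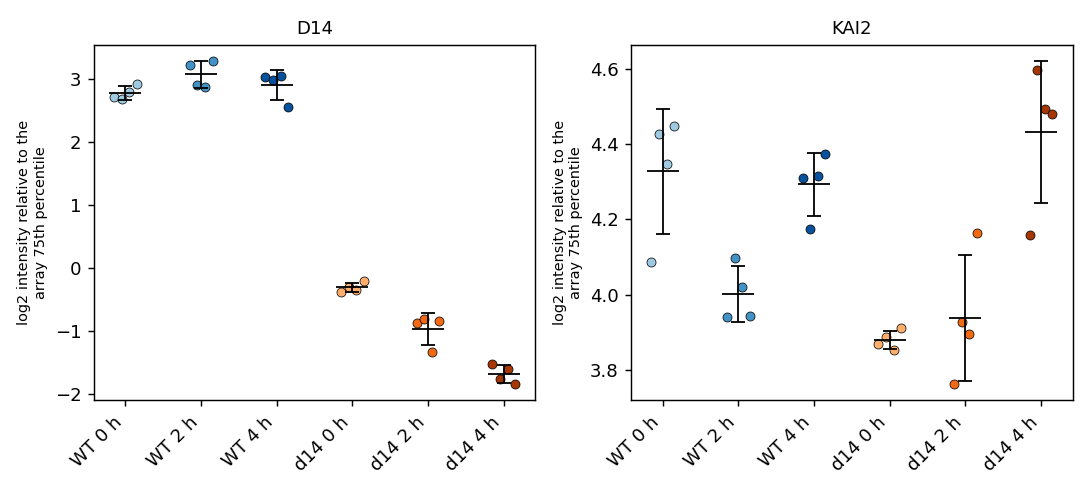
Log2 intensity of D14 and KAI2 relative to the array's 75th percentile for each array, with group mean and SD (n = 4). Every d14 array lies below every WT array for D14, with group means of -0.31 and 2.77 at 0 h.

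Well-watered d14 leaves differed from WT in the strigolactone pathway itself. Of 15 genes of strigolactone and karrikin signalling, 12 fell and 1 rose, with 12 and 1 adjusted over the list alone. D14 fell by 3.08 ± 0.13 on the log2 scale (SE, n = 4 per group here and below). The repressor genes SMXL6, SMXL7 and SMXL8, whose proteins D14 marks for breakdown, fell by 0.66 ± 0.08, 1.16 ± 0.11 and 2.40 ± 0.20, and the branching repressor BRC1 fell by 2.87 ± 0.17. HB40, a homeobox gene that acts below BRC1, fell by 2.95 ± 0.33, while DLK2, a paralog of D14, stood at 0.31 ± 0.19 (adjusted p = 0.186). The list fell in camera (adjusted p = 4.17e-05, and 0.0165 with an estimated correlation). It holds D14 itself, the mutated gene, and was not tested without it. In strigolactone biosynthesis and breakdown 3 of 6 members rose and 2 fell, MAX4, a carotenoid cleavage dioxygenase of the pathway, among those that rose, by 3.34 ± 0.65 (above background on 2 of 4 WT arrays). The list's adjusted p was 0.891.

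Beyond this pathway, 9932 of 19744 genes differed at 0 h, 4555 higher and 5377 lower in d14, and 1580 of them by at least 2-fold (985 higher, 595 lower). Among genes well above background on every array compared, and with no overlap between the groups, the largest rises were of AT5G03545 (3.81 ± 0.30), AT3G42130, SCPL12, UBQ13 and AT1G36240 (3.07 ± 0.11). The largest falls among such genes were of AT4G11290 (-4.55 ± 0.30), the splicing factor gene SR30 (-3.99 ± 0.13), AT5G37940, CYP96A5 and AT1G03010 (-3.14 ± 0.34). Of 42 photosynthesis genes 25 rose and none fell, among them LHCB4.1 (1.13 ± 0.17), PSAE-1 (1.02 ± 0.10) and PSBQ-2 (1.00 ± 0.13). The photosynthesis list rose (adjusted p = 3.01e-06), with adjusted p = 0.795 with an estimated correlation, and it missed the threshold after quantile normalization (adjusted p = 0.161). After rescaling by the spike-in slope the list, photosynthesis, d14 against WT at 0 h, fell (adjusted p = 9.37e-07), and LHCB4.1, PSAE-1 and PSBQ-2 were no longer called. The clock genes LHY and CCA1 rose by 1.72 ± 0.17 and 1.13 ± 0.20, 7 of the 19 clock genes rose and 2 fell, and that list missed the threshold (adjusted p = 0.145). The call of CCA1 ended with the mean of all its probes (0.56). CKX1, which breaks down cytokinin, fell by 2.68 ± 0.37, and 9 of 19 cytokinin genes fell (adjusted p = 0.0718). OST1, a kinase of ABA signalling, fell by 0.74 ± 0.12, but as the mean of all its probes it rose by 0.44. Of the SnRK2 and ABF genes 5 of 8 fell (adjusted p = 0.0612), and of the flower markers 5 of 12 rose (adjusted p = 0.201). MAM3, of aliphatic glucosinolate synthesis, fell by 2.2 ± 0.49 (above background on 2 of 4 d14 arrays), the only called fall in its list of 15. Among the genes named here as changed, the highest adjusted p was that of MAM3, 0.000878. With normexp the genes d14 against WT at 0 h split into 3486 higher and 7698 lower, with centring on the median into 3257 and 7498, and with no filter into 4579 and 9309. Of 4519 genes with several tested probes and at least 1 called, 14.6% had probes called in opposite directions, against 0.176% of 1138 at 4 h. Such a share can rise with the number of calls alone. The share was 18.3% and 16.5% for the WT responses at 2 h and 4 h, 6.67% and 6.97% for those of d14, and 12.2% and 8.37% for the interactions.

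After 2 h of dehydration d14 leaves had higher jasmonate, cuticle, aquaporin, photosynthesis and flower marker transcripts than WT, and lower heat shock transcripts, as lists at camera's preset correlation. None of these lists passed with an estimated correlation. Of 28 jasmonate genes 17 rose and none fell (21 adjusted over the list alone), among them the lipoxygenase LOX4 (1.00 ± 0.23), with adjusted p = 5.44e-07, and 0.306 with an estimated correlation. Of 33 cuticle and wax genes 14 rose, among them the regulator SHN1 (2.69 ± 0.59, above background on 3 of 4 WT arrays) and MAH1 (1.79 ± 0.48), and of 17 aquaporin genes 11 rose and 1 fell, PIP2;5 rising by 1.1 ± 0.23. Their adjusted p were 0.000311 and 0.000175, and with an estimated correlation the adjusted p = 0.629 and 0.608. Of 42 photosynthesis genes 15 rose and none fell (adjusted p = 0.000175, and 0.74 with an estimated correlation). Of 15 heat shock genes 12 fell, 11 of them by at least 2-fold, with HSP17.6C at -4.59 ± 1.06 and HSP17.6A at -3.42 ± 0.85 (above background on 3 of 4 d14 arrays). That list's adjusted p was 7.11e-05, and the adjusted p = 0.306 with an estimated correlation.

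Of 12 flower and inflorescence markers 10 rose at 2 h and none fell, with SEP2 (AT3G02310) at 2.46 ± 0.49, PI at 2.25 ± 0.49 and AP3 at 2.02 ± 0.68, all regulators of floral organs (adjusted p = 7.11e-05, and 0.306 with an estimated correlation). The call of AP3 d14 against WT at 2 h ended without WT replicate 2 or 4 or d14 replicate 2 or 3 (adjusted p = 0.0653, 0.065, 0.0688 and 0.0779). Vascular markers rose too, 8 of 11, with the cellulose synthase IRX3 at 1.09 ± 0.21 (adjusted p = 0.000242, and 0.306 with an estimated correlation). These markers differed in the same comparison as the gene groups above, and a link between them was not tested. MRD1 (6.19 ± 1.19), AT5G62080 (5.79 ± 1.04), AT1G05540 (4.96 ± 0.11), LAP5 (4.16 ± 1.04), which acts in pollen wall formation, and AT3G52130 (4.15 ± 0.83) had the largest rises among genes well above background without overlap. The largest falls among them were of SR30 (-5.11 ± 0.13), HSP17.6C, AACT1 (AT5G61160, -4.21 ± 0.57), D14 and AT4G11290 (-4.03 ± 0.30). Of the anthocyanin genes DFR and LDOX fell by 2.88 ± 0.39 and 2.72 ± 0.44 (LDOX above background on 1 of 4 d14 arrays) and the regulator MYB113 by 2.59 ± 0.36. In that list 9 of 26 members fell and 5 rose, and it was not called (adjusted p = 0.761). Clock genes rose (10 of 19, RVE8 by 0.94 ± 0.22, adjusted p = 0.00666, and 0.306 with an estimated correlation). Stomatal development genes rose (6 of 18, adjusted p = 0.00488, and 0.629 with an estimated correlation). Senescence genes fell (9 of 22, with 2 rising, adjusted p = 0.0236, and 0.629 with an estimated correlation).

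The strigolactone signalling list stayed lower at 2 h, with 6 of 15 genes down and 2 up (adjusted p = 0.0416, and 0.306 with an estimated correlation). D14, the mutated gene, counts among those down, and the list was not tested without it. D14 fell by 4.03 ± 0.13 and BRC1 by 3.26 ± 0.17, SMXL6, SMXL7 and SMXL8 fell by 0.59 ± 0.08, 0.39 ± 0.11 and 0.61 ± 0.20, and MAX4 rose by 2.1 ± 0.65. With normexp SMXL7 d14 against WT at 2 h was not called (-0.16, adjusted p = 0.181), nor was MAX4 d14 against WT at 2 h (0.79, adjusted p = 0.0678). MAX4 was also not called without WT replicate 1 or d14 replicate 2 (adjusted p = 0.0539 and 0.0753). The call of SMXL8 d14 against WT at 2 h ended without WT replicate 2 or 3 (adjusted p = 0.0516 and 0.0565). Of the ABA panel HAI1, RD29A and NCED3 did not pass at 2 h, with HAI1, a protein phosphatase 2C, at -0.03 ± 0.14, RD29A, a dehydration-response gene, at 0.44 ± 0.27 and the ABA synthesis gene NCED3 at -0.02 ± 0.21 (adjusted p = 0.91, 0.216 and 0.949). Of 22 dehydration effectors 1 rose and 2 fell (adjusted p = 0.761), of 9 clade A phosphatases 2 rose (0.566), and of 16 ABA metabolism genes 3 rose and 3 fell (0.919). In all 6336 genes differed at 2 h, 3069 higher and 3267 lower, 877 of them by at least 2-fold (387 and 490). With centring on the median the genes d14 against WT at 2 h split into 2108 higher and 3967 lower, and an adjusted p under 0.01 left 3673.

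After 4 h, d14 leaves had lower cytokinin and indole glucosinolate transcripts than WT and higher flower markers, as lists at camera's preset correlation and not with an estimated one. Of 19 cytokinin genes 8 fell and none rose, with the response regulators ARR16 and ARR15 at -2.88 ± 0.30 and -1.41 ± 0.32 and the oxidase CKX5 at -1.10 ± 0.10 (adjusted p = 0.000303, and 0.158 with an estimated correlation). Of 10 indole glucosinolate genes 5 fell, among them the regulator MYB34 (-1.04 ± 0.14) and the glucosyltransferase UGT74B1 (-0.78 ± 0.15), with adjusted p = 7.78e-05, and 0.349 with an estimated correlation. The aliphatic list fell as well (1 of 15 called, adjusted p = 0.0182, and 0.699 with an estimated correlation). Of 12 flower markers 9 rose, PI by 3.04 ± 0.49, AP3 by 3.05 ± 0.68 (above background on 2 of 4 WT arrays) and SEP2 (AT3G02310) by 2.71 ± 0.49, with adjusted p = 6.67e-06, and 0.213 with an estimated correlation. The flower markers rose where the cytokinin and glucosinolate lists fell, and a link between them was not tested.

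**Figure D4:**
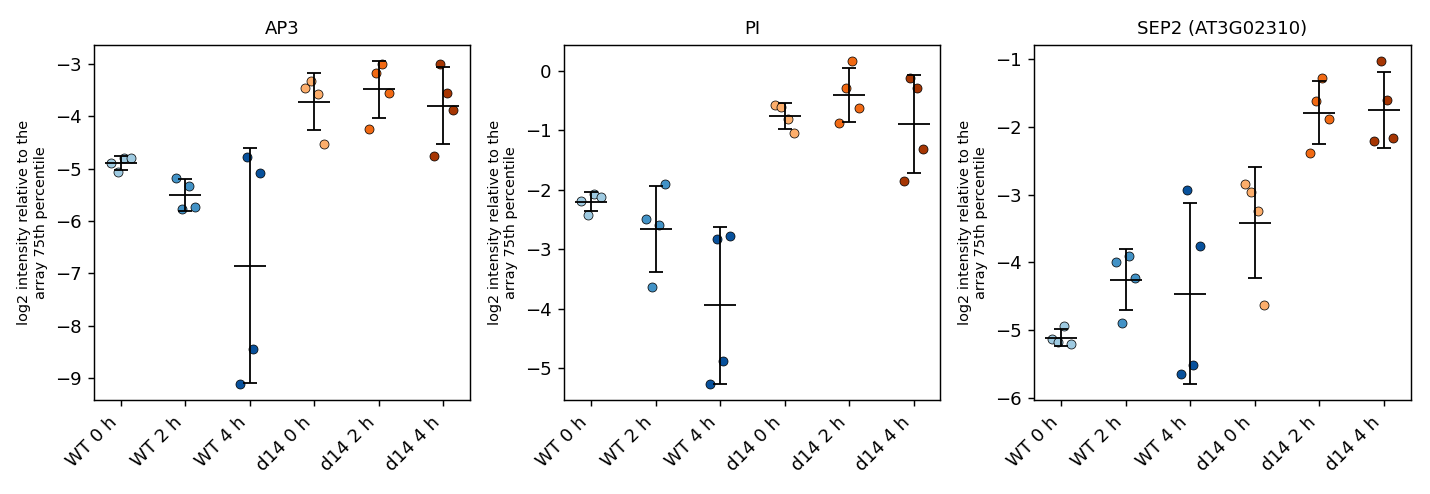
Log2 intensity of the floral regulators AP3, PI and SEP2 (AT3G02310) relative to the array's 75th percentile for each array, with group mean and SD (n = 4). The d14 means lie above the WT means at each time, by 2.25 for PI at 2 h, and the WT 4 h arrays spread widely.

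Of the SnRK2 and ABF genes 3 of 8 rose at 4 h, ABF4 by 0.55 ± 0.06 and SNRK2.3 by 0.30 ± 0.09 (6 adjusted over the list alone, adjusted p = 0.00134, and 0.158 with an estimated correlation). Stomatal development genes rose (7 of 18, 1 fell, SDD1 by 1.05 ± 0.19, adjusted p = 0.0086, and 0.635 with an estimated correlation), as did clock genes (5 of 19, adjusted p = 0.0141, and 0.349 with an estimated correlation). The anthocyanin genes DFR, LDOX and CHS fell by 2.31 ± 0.39, 2.26 ± 0.44 (above background on 2 of 4 d14 arrays) and 1.39 ± 0.28, with 9 of 26 list members down and 5 up (adjusted p = 0.121). D14 fell by 4.58 ± 0.13. BRC1 stood at -3.13 ± 0.17, and SMXL6, SMXL7 and SMXL8 fell by 0.26 ± 0.08, 0.42 ± 0.11 and 0.88 ± 0.20. In all 5 of 15 signalling genes fell (adjusted p = 0.0263, and 0.213 with an estimated correlation). These include D14, and the list was not tested without it. When only the groups compared were fitted, the calls of SMXL6 d14 against WT at 4 h and SNRK2.3 d14 against WT at 4 h ended (adjusted p = 0.114 and 0.129). So did those of AP3 d14 against WT at 4 h and ARR15 d14 against WT at 4 h (adjusted p = 0.0928 and 0.0899). Those of SMXL6 and SNRK2.3 also ended in the fit of the arrays of 1 scan day (adjusted p = 0.0564 and 0.0819). The call of SMXL6 ended with the mean of all its probes (adjusted p = 0.134) and without WT replicate 1 or 2 or d14 replicate 2, 3 or 4 (0.0573, 0.0807, 0.0634, 0.0603 and 0.0817). That of SNRK2.3 ended without WT replicate 1 or 3 or d14 replicate 2, 3 or 4 (adjusted p = 0.0783, 0.0612, 0.0752, 0.0583 and 0.0781). HAI1, RD29A and NCED3 stood at 0.24 ± 0.14, -0.31 ± 0.27 and -0.36 ± 0.21 and did not pass (adjusted p = 0.243, 0.458 and 0.245). Among genes well above background without overlap the largest rises were of AT1G05540 (5.38 ± 0.11), AT5G03545 (3.67 ± 0.30), PI, AT5G19890 (2.84 ± 0.30) and SEP2, and the largest falls of SR30 (-5.53 ± 0.13), D14, AT5G38130 (-3.23 ± 0.34), BRC1 and AT4G11210 (-3.01 ± 0.27). In all 3365 genes differed at 4 h (1788 higher, 1577 lower), 584 by at least 2-fold (293 and 291). The number of genes d14 against WT at 4 h was 2041 without WT replicate 1, 2198 without WT replicate 3 and 2134 without d14 replicate 2, and 1471 at an adjusted p under 0.01.

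A set of genes differed between the genotypes at every time. In d14, 354 genes were higher and 494 lower at 0, 2 and 4 h, where independent lists would share 64.1 and 71.1. These comparisons share no arrays, but in the single fit they share the estimated spread of each gene. Genes of low spread can thus be called at several times together, and the excess over independent lists may be overstated. Of the genes called the same way each time, 48 were at least 2-fold higher and 81 at least 2-fold lower each time (0.287 and 0.218 in independent lists). AT5G03545 (3.81, 3.57 and 3.67 at 0, 2 and 4 h), AT1G05540 (2.92, 4.96 and 5.38), PI and SEP2 (AT3G02310) were among the higher ones, and D14, BRC1 (-2.87, -3.26 and -3.13) and SR30 (-3.99, -5.11 and -5.53) among the lower ones.

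After 2 h of dehydration most of the WT transcriptome differed from 0 h. ABA and jasmonate genes rose as groups at camera's preset correlation, though not with an estimated one. All 22 dehydration and ABA effectors rose, RD29A by 5.14 ± 0.27, RAB18 (AT5G66400), a dehydrin gene, by 3.69 ± 0.15 and TSPO by 9.96 ± 0.25 (above background on 3 of 4 arrays at 0 h). All 9 clade A phosphatase genes rose, HAI1 by 9.01 ± 0.14, and 14 of 16 ABA metabolism genes, NCED3 by 2.99 ± 0.21. Of 18 dehydration transcription factors 15 rose, NAC019 by 5.75 ± 0.11 and HB7 by 5.17 ± 0.10, and of 13 osmolyte genes 11 rose, with P5CS1, of proline synthesis, at 4.43 ± 0.14. Of 28 jasmonate genes 26 rose, CYP94B3 by 8.81 ± 0.47 and LOX3 by 5.88 ± 0.23. The camera adjusted p were 1.06e-11, 2.87e-06, 0.000109, 2.87e-06, 0.0026 and 5.11e-10 in this order, and with an estimated correlation the adjusted p = 0.0698, 0.0936, 0.0698, 0.0698, 0.126 and 0.0754.

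Other groups moved at 2 h in WT too. Heat shock genes rose (14 of 15, adjusted p = 0.000185, and 0.226 with an estimated correlation), as did anthocyanin genes (19 of 26, MYB75 by 7.25 ± 0.22, adjusted p = 0.00116, and 0.134 with an estimated correlation). Aliphatic and indole glucosinolate genes rose too (12 of 15 and 8 of 10, MYB29 by 4.95 ± 0.28 with 3 of 4 arrays above background at 0 h). The glucosinolate lists had adjusted p = 0.0026 and 0.00362, and 0.576 and 0.493 with an estimated correlation. Cell division genes fell (12 of 16, KN, of cytokinesis, by 2.01 ± 0.21, adjusted p = 0.027, and 0.822 with an estimated correlation). The chlorophyll breakdown gene NYE1 rose by 4.86 ± 0.11 and the aquaporin PIP1;4 by 3.84 ± 0.13, while the ABA receptor PYL4 fell by 2.04 ± 0.13, and their lists had adjusted p = 0.0997, 0.13 and 0.5. Photosynthesis genes went both ways, 21 up and 14 down (LHCB4.1 1.88 ± 0.17, RBCS1B -3.64 ± 0.14, adjusted p = 0.5). The list, photosynthesis, WT 2 h against 0 h, fell after quantile normalization (adjusted p = 0.00826) and after rescaling by the spike-in slope (adjusted p = 3.31e-07). The largest rises among genes above background were of HAI1, CYP94B3, NATA1 (8.09 ± 0.72), EDL3 (7.84 ± 0.25) and AT1G69480 (7.63 ± 0.16), with RD20 at 7.60 ± 0.16. XTH15 (-6.23 ± 0.37) and EXPA8 (-6.20 ± 0.43), of cell wall loosening, CYCP4;1 (-5.94 ± 0.24), GER1 (AT1G72610, -5.65 ± 0.20) and AT4G12510 (-5.61 ± 0.44) fell furthest among them. In all 15491 genes changed, 7214 up and 8277 down, 6918 by at least 2-fold (3794 and 3124), and with normexp the genes WT 2 h against 0 h split into 5828 up and 10226 down.

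At 4 h in WT the ABA and jasmonate lists were again higher than at 0 h, and auxin genes were lower, at camera's preset correlation and not with an estimated one. HAI1 rose by 9.21 ± 0.14, TSPO by 11.23 ± 0.25 (above background on 3 of 4 arrays at 0 h), RD20 by 7.87 ± 0.16, RAB18 (AT5G66400) by 4.81 ± 0.15, RD29A by 4.61 ± 0.27, P5CS1 by 5.51 ± 0.14 and NCED3 by 2.84 ± 0.21. Effectors (21 of 22 rose, adjusted p = 6.12e-11), phosphatases (9 of 9, 3.3e-06), ABA metabolism (14 of 16, 6.79e-05), transcription factors (15 of 18, 0.000128), osmolyte genes (10 of 13, 0.00504) and jasmonate genes (26 of 28, 7.36e-08, with VSP1 at 6.58 ± 0.18) rose as lists. With an estimated correlation the adjusted p = 0.0699, 0.125, 0.0699, 0.125, 0.15 and 0.125. Auxin genes fell (14 of 18, IAA29 by 5.23 ± 0.34, adjusted p = 0.0225, and 0.497 with an estimated correlation), and vascular markers rose (10 of 11, adjusted p = 0.0225, and 0.454 with an estimated correlation). Anthocyanin genes (16 of 26, MYB75 6.96 ± 0.22), heat shock genes (13 of 15) and aliphatic glucosinolate genes (13 of 15) rose with adjusted p = 0.0181, 0.0181 and 0.00138, and 0.394, 0.454 and 0.454 with an estimated correlation. NYE1 rose by 5.68 ± 0.11, the clock gene CCA1 by 2.49 ± 0.20 and the wax gene CER1 by 3.69 ± 0.16, and KN fell by 2.07 ± 0.21, in lists that were not called (adjusted p = 0.0587, 0.346, 0.283 and 0.0526). The list, photosynthesis, WT 4 h against 0 h, had adjusted p = 0.061 with 26 of 42 rising. It rose with normexp (adjusted p = 0.00377) and fell after rescaling by the spike-in slope (adjusted p = 4.29e-06). HAI1, NATA1 (9.14 ± 0.72), CYP94B3 (8.90 ± 0.47), RD20 and EDL3 (7.64 ± 0.25) rose furthest among genes well above background on every array compared, and AT5G02760 (-8.80 ± 0.45), XTH15 (-8.00 ± 0.37), EXPA8 (-7.80 ± 0.43), XTH25 (-6.77 ± 0.43) and CYCP4;1 (-6.15 ± 0.24) fell furthest. In all 16317 genes changed, 7449 up and 8868 down, 8260 by at least 2-fold (4075 and 4185).

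In d14 at 2 h, dehydration and ABA lists and jasmonate genes rose as well. Effectors (21 of 22 rose, adjusted p = 1.32e-13), phosphatases (9 of 9, 4.57e-08), transcription factors (17 of 18, 8.67e-09), ABA metabolism (14 of 16, 1.29e-05) and jasmonate genes (26 of 28, 1.83e-13) also passed with an estimated correlation (adjusted p = 0.026, 0.0403, 0.026, 0.0266 and 0.0266). TSPO rose by 10.18 ± 0.25, HAI1 by 9.18 ± 0.14, RD29A by 6.58 ± 0.27, RAB18 (AT5G66400) by 3.90 ± 0.15, NCED3 by 3.71 ± 0.21, NAC019 by 6.57 ± 0.11, P5CS1 by 4.49 ± 0.14 and LOX3 by 6.19 ± 0.23. Cuticle genes rose in d14 (22 of 33, adjusted p = 0.00144, and 0.533 with an estimated correlation), as did SnRK2 and ABF genes (6 of 8, 0.00416, and adjusted p = 0.0771 with an estimated correlation). Aquaporins rose (12 of 17, PIP1;4 by 4.05 ± 0.13, 0.00473, and adjusted p = 0.533 with an estimated correlation), and so did osmolyte genes (10 of 13, 0.000571, and adjusted p = 0.0584 with an estimated correlation). Heat shock (11 of 15), anthocyanin (14 of 26, MYB75 7.86 ± 0.22 with 3 of 4 arrays above background at 0 h), aliphatic (12 of 15) and indole glucosinolate genes (7 of 10) rose and cell division genes fell (15 of 16), with adjusted p = 0.00144, 0.00416, 0.00147, 0.00553 and 0.00147, and 0.34, 0.223, 0.496, 0.496 and 0.533 with an estimated correlation. NYE1 rose by 3.62 ± 0.11 and HB40 by 3.94 ± 0.33. AT5G54165 (9.15 ± 0.26), CYP94B1 (8.92 ± 0.41) and AT3G03341 (8.83 ± 0.27) were among the largest rises of genes well above background on every array compared, and EXPA8 (-6.09 ± 0.43), XTH15 (-6.09 ± 0.37), AT4G16563 (-5.86 ± 0.34), GAT1_2.1 (-5.14 ± 0.48) and CYCP4;1 (-5.01 ± 0.24) were the largest falls. In all 14551 genes changed, 6582 up and 7969 down, 5577 by at least 2-fold (3053 and 2524).

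At 4 h in d14, TSPO rose by 11.63 ± 0.25, AT3G02480 by 11.44 ± 0.19, AT3G03341 by 10.13 ± 0.27, HAI1 by 9.64 ± 0.14 and AT2G37870 by 9.42 ± 0.14. RAB18 (AT5G66400) rose by 5.60 ± 0.15, RD29A by 5.29 ± 0.27, P5CS1 by 5.29 ± 0.14, NCED3 by 3.21 ± 0.21, VSP1 by 6.44 ± 0.18, NYE1 by 4.98 ± 0.11 and MYB75 by 7.34 ± 0.22 (above background on 3 of 4 arrays at 0 h). AT5G02760 (-7.17 ± 0.45), XTH15 (-6.66 ± 0.37), EXPA8 (-6.55 ± 0.43), AT4G16563 (-6.19 ± 0.34) and CYCP4;1 (-5.71 ± 0.24) fell furthest among genes well above background on every array compared, and KN fell by 2.12 ± 0.21. Effectors (21 of 22, adjusted p = 1.86e-12) and ABA metabolism (14 of 16, 1.06e-05) rose, also with an estimated correlation (adjusted p = 0.0404 for both). Phosphatases (9 of 9), SnRK2 and ABF genes (6 of 8), transcription factors (15 of 18), osmolyte genes (11 of 13) and jasmonate genes (26 of 28) rose with adjusted p = 2.36e-07, 0.0019, 6.49e-06, 0.00175 and 4.66e-08, and 0.0643, 0.0643, 0.0643, 0.083 and 0.083 with an estimated correlation. Cuticle genes (19 of 33), senescence genes (12 of 22), heat shock genes (13 of 15) and aliphatic glucosinolate genes (13 of 15) rose with adjusted p = 0.0263, 0.0263, 0.00379 and 0.00175, and 0.637, 0.484, 0.454 and 0.484 with an estimated correlation. All 16 cell division genes fell, and 14 of 18 stomatal development genes, with adjusted p = 0.000379 and 0.0395, and 0.484 and 0.546 with an estimated correlation. In all 15622 genes changed, 7188 up and 8434 down, 7106 by at least 2-fold (3528 and 3578).

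Across genes the WT and d14 responses were compared with each other. Over the 17546 genes called in either genotype at 2 h Pearson's r was 0.892 and Spearman's rho 0.874, with a slope of d14 on WT of 0.942, and over 18019 genes at 4 h these were 0.927, 0.915 and 0.929. Of genes called in both, 96.2% and 97.5% had the same sign. Genes are not independent replicates, and the responses use different control arrays.

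**Figure D5:**
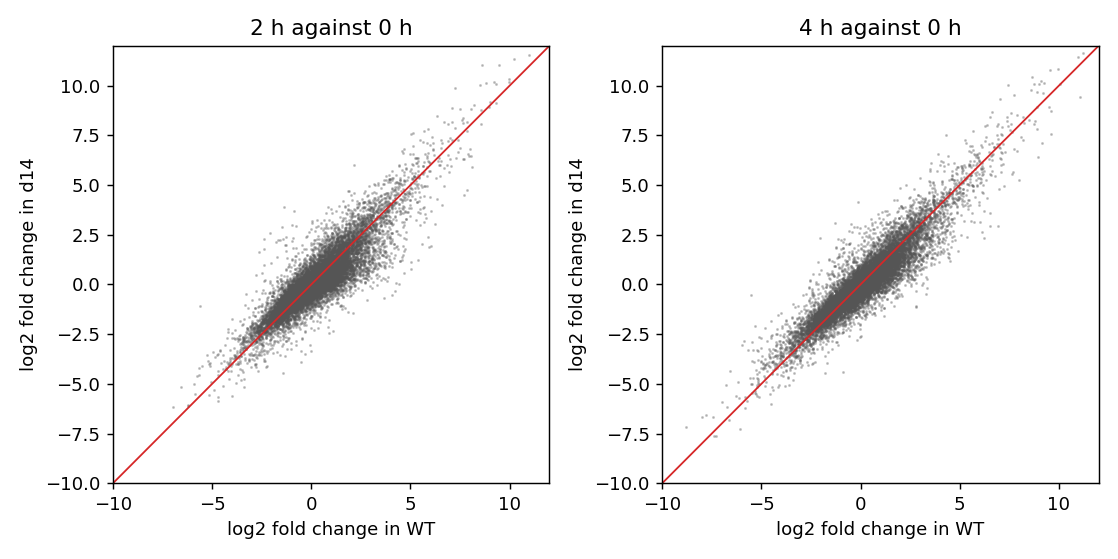
Log2 fold change against 0 h in d14 (y axis) and WT (x axis) at 2 h and 4 h, with 1 point per gene and a line of equal change. Points gather along the line, with r = 0.892 at 2 h and 0.927 at 4 h over genes called in either genotype.

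The test of the difference between the responses found 7064 genes at 2 h (3566 with a higher and 3498 with a lower d14 response), 1657 of them by at least 2-fold (597 and 1060). Cuticle and wax genes responded more in d14 (17 of 33 higher, none lower), with MAH1, a wax enzyme, at 4.68 ± 0.69 and KCS1 at 1.86 ± 0.31 (adjusted p = 8.31e-05, and 0.835 with an estimated correlation). So did 13 of 28 jasmonate genes (1 lower, adjusted p = 0.0116, and 0.835 with an estimated correlation). RD29A (1.43 ± 0.38), CYP707A3, of ABA breakdown (1.44 ± 0.22), SMXL8 (1.79 ± 0.28) and HB40 (2.22 ± 0.46) had a higher change from 0 h to 2 h in d14 than in WT. D14 (-0.95 ± 0.18) and GSTF12, of anthocyanin transport (-4.42 ± 0.60, above background on 1 of 4 WT arrays at 0 h), had a lower one. The mean of the brightest D14 probe went from 2.772 to 3.068 in WT and from -0.305 to -0.963 in d14. The call of D14 interaction at 2 h ended after rescaling by the spike-in slope (-0.38). HAI1, NCED3 and P5CS1 stood at 0.17 ± 0.20, 0.71 ± 0.29 and 0.07 ± 0.20 (adjusted p = 0.527, 0.064 and 0.823). The value of NCED3 interaction at 2 h was called after quantile normalization (0.79, adjusted p = 0.0422) and centring on the median (0.0435). It was also called without WT 2 h replicate 1, d14 0 h replicate 1 or d14 0 h replicate 3 (0.0316, 0.0407 and 0.0455). Among genes well above background on every array compared, the largest differences were those of MAH1, AT5G37940 (4.16 ± 1.06), ADS4 (3.24 ± 0.65), AT2G44578 (2.85 ± 0.34), GolS3 (2.81 ± 0.58), AT3G42130 (-4.34 ± 0.32), AT1G36240 (-3.91 ± 0.16), PAD3 (-3.61 ± 1.03), UBQ13 (-3.51 ± 0.10) and SCPL12 (-3.43 ± 0.17). AT3G42130, AT1G36240, UBQ13 and SCPL12 were also among the 5 largest rises named in d14 at 0 h, and this difference holds the WT 0 h slide. With normexp the calls counted as genes interaction at 2 h split into 5759 higher and 3337 lower, and with no filter into 6530 and 3515. The list, photosynthesis, interaction at 2 h, was not called (14 of 42 lower, 2 higher, adjusted p = 0.124), was lower in d14 with normexp (adjusted p = 0.0156) and higher after rescaling by the spike-in slope (adjusted p = 1.3e-09).

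At 4 h 6552 genes differed in response (3441 higher, 3111 lower in d14), 1431 by at least 2-fold (509 and 922). SnRK2 and ABF genes responded more in d14 (7 of 8), ABF4 by 0.90 ± 0.08 and OST1 by 1.05 ± 0.17 (adjusted p = 0.000634, and 0.099 with an estimated correlation), and as the mean of all its probes OST1 stood at -0.16. Cuticle genes (15 of 33, MAH1 4.34 ± 0.69) and strigolactone signalling (9 of 15, 1 lower) responded more, with adjusted p = 0.00251 and 0.0272, and 0.97 and 0.346 with an estimated correlation. At 0 h 16 of 33 cuticle genes were lower in d14 and 8 higher (adjusted p = 0.129). The means of this list in d14 against WT were -0.338 at 0 h, 0.405 at 2 h and 0.274 at 4 h, so much of its interactions (0.743 at 2 h and 0.612 at 4 h) comes from the 0 h arrays. For strigolactone signalling these means were -1.139 at 0 h and -0.54 at 4 h, so the gap between the genotypes narrowed, and for SnRK2 and ABF genes they were -0.327 and 0.288. SMXL8 and HB40 stood at 1.52 ± 0.28 and 2.55 ± 0.46 and D14 at -1.5 ± 0.18. Photosynthesis (21 of 42 lower, LHCB4.1 -1.14 ± 0.24, PSBQ-2 -1.14 ± 0.18), cell division (8 of 16) and indole glucosinolate genes (5 of 10) had a lower change from 0 h to 4 h in d14 than in WT. Their adjusted p were 1.27e-06, 0.00462 and 0.0247, and 0.97 for each with an estimated correlation. Their means in d14 against WT were 0.387, 0.363 and 0.057 at 0 h and -0.036, -0.192 and -0.672 at 4 h, so nearly all of the photosynthesis difference comes from the 0 h arrays. The mean of the cell division list fell from 0 h to 4 h in both genotypes, further in d14. The list, photosynthesis, interaction at 4 h, turned after rescaling by the spike-in slope (adjusted p = 2.36e-06, higher in d14), where LHCB4.1 and PSBQ-2 were not called. The value of CYCB2;1 interaction at 4 h was -1.27 ± 0.48 (adjusted p = 0.0496, above background on 1 of 4 WT arrays at 0 h and on no array at 4 h, so not a measured size) and turned to 0.33 with normexp. Its call also ended after quantile normalization and centring on the median (adjusted p = 0.073 and 0.0621), and without single arrays, the highest adjusted p being 0.114 without d14 4 h replicate 3. HAI1 and NCED3 did not pass (0.44 ± 0.20 and 0.37 ± 0.29, adjusted p = 0.0916 and 0.352). The value of HAI1 interaction at 4 h was called with normexp (0.54, adjusted p = 0.00726), quantile normalization (0.0159) and centring on the median (0.0249). It was also called without d14 0 h replicate 2 or d14 4 h replicate 4 (0.0238 and 0.0429). XTH18 (2.74 ± 0.65), AGP22 (2.54 ± 0.47), AT1G05540 (2.46 ± 0.16), AT3G42130 (-3.52 ± 0.32), AT1G36240 (-3.15 ± 0.16), SCPL12 (-3.01 ± 0.17), UBQ13 (-2.87 ± 0.10) and CCT1 (-2.83 ± 0.15) complete the largest differences among genes well above background on every array compared. With normexp the calls counted as genes interaction at 4 h split into 5638 higher and 2365 lower, with centring on the median into 5177 and 2186, and with no filter into 6463 and 3139.

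Between 2 h and 4 h, a comparison without any 0 h array, jasmonate genes fell in d14 (22 of 28, LOX3 by 3.07 ± 0.23, adjusted p = 2.5e-06, and 0.519 with an estimated correlation). LOX3 fell by 1.71 ± 0.23 in WT. The difference between the genotypes was called for 1227 genes (655 higher, 572 lower), 274 by at least 2-fold (133 and 141). As a list, jasmonate genes had a lower change from 2 h to 4 h in d14 than in WT (14 of 28 lower, none higher, CYP94C1 -1.80 ± 0.22, LOX4 -1.5 ± 0.32, LOX3 -1.36 ± 0.33, adjusted p = 4.14e-12). So did the lists of aquaporins (7 of 17 lower, PIP2;2 -1.29 ± 0.33, TIP1;1 -1.19 ± 0.33, 3.27e-08) and photosynthesis genes (5 of 42 lower, SBPASE -0.81 ± 0.19, 1.45e-06). The change was higher in d14 for the lists of heat shock genes (4 of 15, HSP17.6C 5.29 ± 1.5, 5.99e-06), and of SnRK2 and ABF genes (2 of 8, ABF4 0.43 ± 0.08, 0.00124). With an estimated correlation the adjusted p = 0.108, 0.239, 0.609, 0.203 and 0.108. HAI1 stood at 0.27 ± 0.20 (adjusted p = 0.445). AT4G16260 (3.99 ± 0.89), FAR8 (2.76 ± 0.43), LSU1 (2.72 ± 0.62), AT5G08760 (2.35 ± 0.59), AT1G19320 (-3.26 ± 0.79), MAPKKK21 (-2.75 ± 0.68), ProT3 (-2.65 ± 0.51), AT2G44578 (-2.54 ± 0.34) and AT5G15660 (-2.28 ± 0.61) were other large differences among genes well above background on every array compared. The calls of HSP17.6C, TIP1;1, PIP2;2 and AT5G15660 ended when only the groups compared were fitted. Single arrays moved the number counted as genes interaction 4 h against 2 h, to 608 without WT 4 h replicate 1, 667 without WT 4 h replicate 3 and 743 without d14 2 h replicate 3. It was 2628 without d14 4 h replicate 1, 624 without d14 4 h replicate 2 and 769 without d14 4 h replicate 3. With centring on the median the split was 795 higher and 322 lower, and with the mean of all probes 602 and 842. In all 10661 genes changed between 2 h and 4 h in WT (5097 up, 5564 down) and 10350 in d14 (5022 up, 5328 down).

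Reference genes were not called as a list between the genotypes. In d14 against WT 3 of 8 fell at 0 h and at 2 h and none rose (adjusted p = 0.556 and 0.336), and at 4 h 1 rose and 2 fell (adjusted p = 0.585). Guard-cell function (3 up and 3 down of 12 at 0 h, adjusted p = 0.849), ABA receptors (2 up of 9, adjusted p = 0.816), salicylate and defence (none of 18, adjusted p = 0.849) and antioxidant enzymes (3 up and 1 down of 8, adjusted p = 0.406) were not called between the genotypes at 0 h. Nor were the markers of shoot meristem (none of 6, adjusted p = 0.891), epidermis and trichome (1 up and 1 down of 7, adjusted p = 0.849) and root (2 down of 4, adjusted p = 0.626).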

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

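The tests of signal compression by spike-in rescaling, of anther and tapetum genes and of probes called in opposite directions, and the comparisons of 4 h against 2 h, were tests chosen only after the result was seen.

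The first pattern weighed is the large number of genes that differed between the genotypes at 0 h (9932), against 3365 at 4 h, with the WT 0 h slide apart from the others in its spike-in slope. Uniform compression of signal on that slide was tested by rescaling with the spike-in slope, which raised the number from 9932 to 12898. The number thus did not come down to under 1.5 times that at 4 h, as this explanation asked. Because the rescaling added differences between the groups, it cannot decide on compression. Base composition is argued against, with a Spearman rho of -0.0622 between probe GC content and fold change. Differences between slides that act probe by probe are a candidate explanation for part of it, because 14.6% of genes with several tested probes and at least 1 called had probes called in opposite directions, against 2.03% at 2 h and 0.176% at 4 h. The share was also high in other comparisons with WT at 0 h, 18.3% and 16.5% for the WT responses and 12.2% and 8.37% for the interactions, against 6.67% and 6.97% for the d14 responses, which do not use it. Such a share can rise with the number of calls alone. Genes with a called probe numbered 4519 at 0 h, 3351 at 2 h and 1138 at 4 h, so the later times are not a like baseline. The d14 responses had more such genes (5398 and 5599) and lower shares than d14 against WT at 0 h. Slide and group cannot be told apart here, as each group lies on its own slide. A genotype effect stays open and was not tested apart from the slide.

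The second pattern is the rise of flower and inflorescence markers in d14. Inflorescence tissue among the d14 leaves may account for part of it, tested on 13 anther and tapetum genes in no other list and taken without a filter. With values under the floor of an array set to that floor, their median log2 fold change at 2 h was 1.076 (-0.014 to 4.35), narrowly over the 1 asked of this explanation. It was 0.749 at 4 h, and without the floor these medians were 1.849 and 0.826. At 0 h the WT arrays had a higher floor, which alone gives genes dim in both genotypes -0.925, so that time decides nothing here. On at least 1 array of the 2 h groups 12 of the 13 were above background in d14 and 4 in WT. Most are dim, ACOS5 and A9 standing at -2.7 and -3.45 in d14 at 2 h, far under the 75th percentile of the arrays. A share of such tissue that varies between plants is also consistent with the data, since 6 floral regulators had a mean pairwise correlation of 0.695 over the 12 d14 arrays centred on their groups (0.346 to 0.902). In WT at 4 h the mean of the flower marker list also ranged from -4.131 to -2.808, so such spread was not particular to d14. Floral genes switched on in d14 leaves themselves could vary together too, were not tested and stay open.

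The third pattern is the 129 genes at least 2-fold higher or lower in d14 at every time. An explanation by neighbouring genes anywhere in the genome was tested by counting pairs within 5 tested genes of each other. There were 7 adjacent pairs among the genes, between the median of 4 and the 95th percentile of 8 in 10000 random sets (highest 14), which leaves it undecided. The count did not look around D14 (AT3G03990), the mutated gene. Most of the 129 genes lie on other chromosomes, and the closest to D14 in locus order were SEP2 (AT3G02310) and AT3G07450. These positions argue against a stretch of other parentage around D14 as the source of the set. A genotype effect stays open, untested.

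Other splits of the same arrays were counted for each number of genes. For d14 against WT, 1 of 35 splits, the real one, gave as many genes at 0 h (9932, highest other 2338), at 2 h (6336, 59) and at 4 h (3365, 3204). This share is under 0.05, and 1 of 35 is the lowest that these splits can give. The real split is also the split by slide, so it does not part genotype from slide. At 4 h exchanging WT replicate 4 and d14 replicate 1 came close. The same holds for WT at 2 h (15491, highest other 2269) and 4 h (16317, 2), d14 at 2 h (14551, 234) and 4 h (15622, 6066), and 4 h against 2 h in WT (10661, 883) and d14 (10350, 2865). For the interactions, 3 of 100 splits gave at least 7064 genes at 2 h (highest other 7234), 4 of 100 at least 6552 at 4 h (highest other 7631) and 2 of 100 at least 1227 for 4 h against 2 h (highest other 2299). These shares are under 0.05, but the splits exchange the genotypes within each time. They thus do not cancel the genotype difference that the times share, as the real contrast does. A split that exchanges most arrays at only 1 time adds that difference. A difference in response alone is not what they test, so chance is not excluded for the interactions. Why some splits gave more genes than the real one was not tested.

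The d14 and WT responses differed in a test of the difference for 7064 genes at 2 h, 6552 at 4 h and 1227 between 2 h and 4 h. The lists that differed had adjusted p = 8.31e-05 (cuticle and wax) and 0.0116 (jasmonate) at 2 h. At 4 h they were strigolactone signalling (0.0272), SnRK2 and ABF genes (0.000634), photosynthesis (1.27e-06), cuticle and wax (0.00251), cell division (0.00462) and indole glucosinolates (0.0247). Between 2 h and 4 h they were SnRK2 and ABF genes (0.00124), photosynthesis (1.45e-06), senescence (0.0279), jasmonate (4.14e-12), heat shock (5.99e-06), cytokinin (0.00124), cell division (0.00139), aquaporins (3.27e-08), indole glucosinolates (0.0285) and vascular markers (0.00855). None of these list differences passed with an estimated correlation, where the lowest adjusted p were 0.835 at 2 h, 0.099 at 4 h and 0.108 between 2 h and 4 h.

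Among genes at 2 h the log2 differences were 4.68 for MAH1, 4.16 for AT5G37940, 3.24 for ADS4, 2.85 for AT2G44578, 2.81 for GolS3, 2.22 for HB40, 1.86 for KCS1, 1.79 for SMXL8, 1.44 for CYP707A3 and 1.43 for RD29A. The negative ones were -0.95 for D14, -3.43 for SCPL12, -3.51 for UBQ13, -3.61 for PAD3, -3.91 for AT1G36240, -4.34 for AT3G42130 and -4.42 for GSTF12 (above background on 1 of 4 WT arrays at 0 h). At 4 h they were 4.34 for MAH1, 2.74 for XTH18, 2.55 for HB40, 2.54 for AGP22, 2.46 for AT1G05540, 1.52 for SMXL8, 1.05 for OST1 and 0.90 for ABF4, and on the other side -1.14 for PSBQ-2 and LHCB4.1, -1.27 for CYCB2;1 (above background on no array at 4 h), -1.5 for D14, -2.83 for CCT1, -2.87 for UBQ13, -3.01 for SCPL12, -3.15 for AT1G36240 and -3.52 for AT3G42130. Between 2 h and 4 h they were 5.29 for HSP17.6C, 3.99 for AT4G16260, 2.76 for FAR8, 2.72 for LSU1, 2.35 for AT5G08760 and 0.43 for ABF4. Those below 0 were -0.81 for SBPASE, -1.05 for MYB34, -1.18 for CKX5, -1.19 for TIP1;1, -1.29 for PIP2;2, -1.36 for LOX3, -1.5 for LOX4, -1.80 for CYP94C1, -2.28 for AT5G15660, -2.54 for AT2G44578, -2.65 for ProT3, -2.75 for MAPKKK21 and -3.26 for AT1G19320.

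In 20 of 246 groups of 4 values a single array lay further from the others than Dixon's critical value for 4 samples allows, where chance gives about 12.3. These arrays had a maximum signal of 610220 intensity units in WT at 4 h, a spike-in slope of 0.936 in d14 at 0 h, and D14 levels on its brightest probe of 2.55 in WT at 4 h and -1.33 in d14 at 2 h. List means on single arrays (log2) were, in d14 at 4 h, -0.14 for ABA metabolism, -0.012 for ABA receptors, -1.66 for auxin and -4.25 for root markers. In WT at 4 h they were 2.2 for clade A phosphatases, -0.66 for guard-cell function, -1.21 for heat shock, 3.58 for aquaporins and -0.037 for aliphatic glucosinolates. In d14 at 0 h they were 0.82 for salicylate and defence, 3.08 for aquaporins and 0.11 for vascular markers. Those in d14 at 2 h were 3.03 for antioxidant enzymes and 0.60 for epidermis and trichome markers, and in WT 0.23 for senescence at 0 h and 3.67 for reference genes at 2 h.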

How the results depend on the processing

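The spike-in rescaling, the fits of 1 scan day and the comparisons of 4 h against 2 h were tests chosen only after the result was seen. Apart from fits that left out an array, 272 counts of genes stayed within 1.5 times the reported count, 28 were higher and 20 lower. Of gene-list results 4480 kept their direction and side of the threshold, 105 gained a call, 144 lost it and 7 reversed, and for named genes these numbers were 2696, 6, 35 and 3. Without 1 array, 228 counts stayed within 1.5 times, 2 were higher and 10 lower. The cause was not tested, except that testing all probes tests more features and that a stricter threshold or filter leaves fewer. Signal over background limits WT at 0 h most, with 63.8% of spots well above background. The median log2 fold change of all genes was -0.12 over genes WT 4 h against 0 h and became -0.301 with normexp and -0.39 with no filter. Centring on the median gave -0.179 over genes d14 against WT at 0 h and 0.189 over genes interaction at 4 h. Directions are relative to the normalization.

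With all probes there were 15401 genes d14 against WT at 0 h, 10533 genes d14 against WT at 2 h, 24491 genes WT 2 h against 0 h, 25537 genes WT 4 h against 0 h, 22494 genes d14 2 h against 0 h and 24312 genes d14 4 h against 0 h. The same setting gave 11781 genes interaction at 2 h, 10084 genes interaction at 4 h, 16159 genes WT 4 h against 2 h and 2996 genes interaction 4 h against 2 h (1139 higher, 1857 lower). At an adjusted p under 0.01 there were 3673 and 1471 genes d14 against WT at 2 h and genes d14 against WT at 4 h, and 4451, 3993 and 275 for the interactions at 2 h, 4 h and 4 h against 2 h. Spike-in rescaling gave 10332 for the interaction at 4 h and 733 for 4 h against 2 h, where normexp gave 2540. Centring on the median split the genes d14 4 h against 2 h into 6764 higher and 3727 lower (reported 5022 and 5328).

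At 2-fold the changes were larger, and counts over all probes are again of probes, not genes. The number of genes of at least 2-fold d14 against WT at 0 h was 534 with normexp, 889 above background on all 24 arrays, 2853 over all probes, 4151 with no filter (1007 higher, 3144 lower) and 3713 after spike-in rescaling (2805, 908). Median centring gave 758 and 854 (reported 985, 595). For genes of at least 2-fold d14 against WT at 2 h these were 386, 423 and 1347 under the first 3 settings, and for genes of at least 2-fold d14 against WT at 4 h 194 and 272 under the first 2. All probes gave 11551 genes of at least 2-fold WT 2 h against 0 h, 13305 genes of at least 2-fold WT 4 h against 0 h, 8918 genes of at least 2-fold d14 2 h against 0 h and 11185 genes of at least 2-fold d14 4 h against 0 h. No filter gave 10926 for the first (3846 up, 7080 down, reported 3794, 3124) and split the next into 4191 and 6655 (reported 4075, 4185). Normexp gave 1108 genes of at least 2-fold WT 4 h against 2 h and 1126 genes of at least 2-fold d14 4 h against 2 h, the latter split into 1015 and 872 by median centring (reported 760, 1188).

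In the counts that follow, those over all probes are also of probes, not genes. The number of genes of at least 2-fold interaction at 2 h was 889 with normexp (452 higher, 437 lower, reported 597, 1060), 988 above background on all arrays, 3230 over all probes, 3898 with no filter (2814, 1084) and 3518 after spike-in rescaling (880, 2638). For genes of at least 2-fold interaction at 4 h these were 626 (344, 282, reported 509, 922), 853, 2660, 3819 (2877, 942) and 3628, and median centring gave 740 and 705. For genes of at least 2-fold interaction 4 h against 2 h there were 98 at an adjusted p under 0.01, 175 above background on all arrays and 670 over all probes (239, 431), and median centring gave 157 and 97 (reported 133, 141). Among WT and d14 responses across genes, correlation at 2 h was 0.836 with no filter, and for WT and d14 responses across genes, correlation at 4 h it was 0.879, and 0.899 after spike-in rescaling. For WT and d14 responses across genes, slope at 2 h was 0.857 and 0.789 in this order, and for WT and d14 responses across genes, slope at 4 h, 0.886 and 0.802.

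As the mean of all probes OST1 d14 against WT at 0 h reversed to 0.44 and OST1 interaction at 4 h to -0.16, and with normexp CYCB2;1 interaction at 4 h reversed to 0.33. The list, photosynthesis, WT 2 h against 0 h reversed with quantile normalization (adjusted p = 0.00826). Spike-in rescaling reversed this list too (3.31e-07), the list, photosynthesis, d14 against WT at 0 h (9.37e-07), the list, photosynthesis, WT 4 h against 0 h (4.29e-06), the list, photosynthesis, interaction at 2 h (1.3e-09), the list, photosynthesis, interaction at 4 h (2.36e-06) and the list, reference genes, interaction at 2 h (0.0486). Leaving out 1 array gave 2041 to 4484 genes d14 against WT at 4 h, 608 to 2628 genes interaction 4 h against 2 h and 169 to 503 genes of at least 2-fold interaction 4 h against 2 h. The last was 503 without d14 4 h replicate 1, 171 without WT 4 h replicate 1 and 169 without d14 4 h replicate 2.

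Replicate numbers did not pair the samples, as the lowest correlation of same-numbered deviations in 14 of 15 pairs of groups was below 0, and in all 10 pairs without d14 at 0 h, whose numbers are in doubt. With these numbers as a block there were 9827 genes d14 against WT at 0 h and 3286 genes d14 against WT at 4 h. The block added the calls of NCED3 interaction at 2 h (adjusted p = 0.0319), of the list, cell division, d14 against WT at 4 h (0.0439) and, in WT at 4 h against 0 h, of photosynthesis, stomatal development and cell division, and changed the call of no other gene list or named gene tested. Slide as a block was not run, because each group lies on its own slide.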

Other observations

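The comparisons of 4 h against 2 h were tests chosen only after the result was seen. Between 2 h and 4 h in WT, auxin genes fell (13 of 18, 2 rose, IAA29 at -3.72 ± 0.34, SE, n = 4 per group), as did indole glucosinolate genes (8 of 10, the regulator MYB34 at -1.99 ± 0.14). Their adjusted p in limma's camera were both 0.0103. Markers of phloem and xylem rose (9 of 11, the xylem protease gene XCP1 by 1.73 ± 0.23, adjusted p = 0.0103), and so did photosynthesis genes (13 of 42, 1 fell, LHCB2.1 by 1.01 ± 0.12, adjusted p = 0.0401). Heat shock genes fell (8 of 15, 1 rose, with the heat shock factor gene HSFA2 at -2.48 ± 0.40, adjusted p = 0.0401). With an estimated correlation the adjusted p = 0.929 for each of these lists. Beyond that, the list, photosynthesis, WT 4 h against 2 h was not called after quantile normalization (adjusted p = 0.475), spike-in rescaling (0.662), with no filter (0.0713) or in 5 of 8 fits that left out 1 array (up to 0.141). The list, heat shock, WT 4 h against 2 h was not called after quantile normalization (0.0556), when only the groups compared were fitted (0.0627) or in 5 of 8 fits that left out 1 array (up to 0.099).

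In d14 over the same interval IAA29 fell by 3.57 ± 0.34 and MYB34 by 3.04 ± 0.14. Auxin genes (13 of 18, 1 rose) and indole glucosinolate genes (8 of 10) fell with adjusted p = 0.00151 and 0.000441, and aquaporin genes fell (14 of 17, adjusted p = 0.000776). Cell division genes fell (6 of 16, 1 rose, adjusted p = 0.0458). Senescence genes rose (11 of 22, 2 fell, adjusted p = 0.00737), with the sugar transporter gene SWEET15 at 5.67 ± 0.52 and DIN2 at 5.91 ± 0.76. SnRK2 and ABF genes rose (5 of 8, 1 fell, adjusted p = 0.028), and dehydration effectors rose (10 of 22, 3 fell, XERO1 by 3.64 ± 0.27, adjusted p = 0.0458). With an estimated correlation the adjusted p = 0.566, 0.566, 0.705, 0.916, 0.566, 0.519 and 0.782 in this order. In d14 the calls of cell division genes, of effectors and of SnRK2 and ABF genes also ended after quantile normalization and spike-in rescaling. Those of cell division genes and effectors ended with the deposited values too, and without single arrays. In the test of the difference between the genotypes few members of the lists were called. The list of cytokinin genes was lower in d14 relative to other genes (2 of 19 called, CKX5 -1.18 ± 0.14, adjusted p = 0.00124), as were those of indole glucosinolate genes (2 of 10, MYB34 -1.05 ± 0.19, adjusted p = 0.0285), phloem and xylem markers (3 of 11, adjusted p = 0.00855) and cell division genes (1 of 16, adjusted p = 0.00139). The senescence list was higher, with 1 of 22 genes called (adjusted p = 0.0279). With an estimated correlation the adjusted p = 0.203, 0.707, 0.464, 0.707 and 0.609. The calls of indole glucosinolate and senescence genes in this test also ended with normexp and without single arrays.

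The medians of the columns of the deposited table, for replicates 1 to 4, were 0.314, 0.28, 0.315 and 0.33 in WT at 0 h, -0.0715, -0.0632, -0.0809 and -0.0268 in WT at 2 h, and -0.113, 0.0591, -0.0575 and 0.0325 in WT at 4 h. In d14 they were 0.0846, 0.132, -0.0367 and -0.0895 at 0 h, -0.0655, -0.0393, -0.0532 and -0.0118 at 2 h, and -0.085, 0.0649, 0.0133 and -0.002 at 4 h. In the d14 0 h group the columns of replicates 1 and 3 matched each other's arrays (r = 0.99999 against 0.898 with their own), as did those of replicates 2 and 4 (r = 1 against 0.828). As these arrays belong to 1 group, group means do not depend on it, while the fit with the replicate number as a block does.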
